A study of Rattus norvegicus with 72 samples.

How the data were processed

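RNA from mammary gland, liver and adipose tissue of pregnant and lactating rats was measured on 72 Affymetrix whole-genome rat arrays, which carry short probes grouped into probe sets. The authors deposited 1 table with a value for 31042 probe sets on every array, and 0 columns of it were left unused. Per the labels these values are log2 signals from RMA, which corrects background, applies quantile normalization and summarises each probe set by median polish. Neither the version of RMA nor the arrays that were processed together were stated. Per the labels, RNA was extracted with TRIzol from mammary gland and liver and with the RNeasy Lipid kit from adipose tissue, and 25 ng of total RNA was amplified and labelled with the NuGEN Ovation Biotin system. Control probe sets were not among the deposited values.

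Array medians ran from 4.32 to 4.56 on the log2 scale in the 60 arrays of the standard gravity and hypergravity groups and from 4.87 to 5.02 in the 12 arrays of the microgravity set. Upper quartiles ran from 6.53 to 7.19 in the former and from 7.43 to 7.52 in the latter. The offset is what separate normalization would leave, so levels were not compared between the sets, and only differences within a set were. For arrays the number of replicates limits the precision, and each group held 4 or 5.

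Groups were taken from the sample labels. In the standard gravity and hypergravity groups, titles carry a tissue letter and a rat code (as in M216S) that recurs in all 3 tissues. Arrays of 1 group were therefore treated as separate animals. The codes were checked at 4 to 6 probe sets per rat at which the arrays of every tissue fell into 2 states, with a gap over 1 log2 unit and at least 3 rats on each side. The rat under test did not enter this choice, and at most 1 other rat could differ in state between tissues. Mammary and adipose arrays showed the state of the liver array of the same code at 98.2% of these probe sets and that of other codes at 53.6% (38 arrays, all but M210H and A210H). Other livers matched at least as well for all rats but 214S and 59H (17 for M48S, itself at 2 of 4). The check thus does not single out a rat. The labels do not say whether letters A to D of the microgravity set are separate animals, so each array was treated as a replicate.

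Differences were tested with limma 3.58.1 in R 4.3.3 (lmFit and eBayes with default settings, group means model). The 20 arrays of a tissue in the standard gravity and hypergravity groups shared 1 fit, the 60 arrays of the 3 tissues shared 1 fit for differences between tissues, the 12 arrays of the microgravity set shared 1 fit, and 22 pregnant mammary arrays shared 1 fit for the contrast of microgravity with hypergravity. P-values are two-sided and were adjusted by Benjamini and Hochberg over the 31042 probe sets within each comparison. A probe set is called where the adjusted p is under 0.05. Standard errors (SE) of log2 fold changes are the moderated ones of limma, and group values are mean log2 signal ± SD. A difference of stage effects between gravities or tissues was tested as an interaction contrast. No probe set was filtered out.

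Probe sets were named from the GEO annotation of the platform: 20826 carried 1 gene symbol, 436 several and 9780 none. The single-symbol probe sets covered 14217 symbols, and 20758 of them had a gene identifier present in the RefSeq table of the GRCr8 assembly, which gave gene positions. A named gene has the value of its single-symbol probe set with the highest mean over the arrays of the fit.

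Gene lists for 33 pathways, hormone responses and cell type markers were written before the data were examined, as were the groups, the comparisons, the tests, the rule for naming genes and most of the repeats with other settings. Of 517 list members 468 had a probe set. Each list was tested with limma camera (preset inter-gene correlation 0.01, brightest probe set per gene, two-sided, adjusted over the 33 lists within a comparison), which compares a list with all other genes. Beside it, camera was run with a correlation estimated for each list. Members called within a list are counted with adjustment over all probe sets and, where given, adjusted over the list alone.

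Genes were named by this rule. For stage comparisons at standard gravity, all hypergravity comparisons and microgravity against the flight control, up to 6 genes in each direction with the largest fold change were taken among called genes for which every array of 1 group lay above every array of the other. Up to 3 in each direction were taken for the other comparisons. Contrasts of 4 groups used the adjusted p alone. For each described list, up to 4 called members with the largest change were taken, or, where none was called, up to 2 with the smallest p, as values only. Csn2, Lalba, Wap, Prlr and Elf5 in mammary gland and Bmal1, Clock, Per1, Per2, Nr1d1 and Dbp in the stage comparisons were always included.

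Each comparison was repeated with array weights, with trend and robust variance, with each array centred on its median, with quantile normalization applied again, without the dimmest 40% of probe sets, with only the groups compared, with the rat code or letter as a block, with the mean of all probe sets of a gene, and without each array in turn. Alternatives chosen after seeing the data left out M210H and A210H, or left out all arrays with skeletal muscle or hepatocyte marker means over 2 log2 units above the median of their tissue and set together with M210H and A210H. The overlaps of calls under each alternative were also added then. Up to 100 splits of the arrays into groups of the same sizes were refitted per comparison.

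The pipeline was tested on simulated data with 200 changed probe sets per comparison. Changes of 2 log2 units were recovered at 89.4% in the mammary stage contrast at standard gravity, 100% in liver and 87.9% in adipose tissue, and changes of 1 log2 unit at 44.8%, 80.6% and 61.2%. Microgravity against the flight control gave 98.5% and 83.6%. A shifted list was called in 22 of 22 simulations and 0 of 704 unchanged lists were. Splits of the real arrays gave up to 18 lists, so false calls can exceed this. Correlations (100000 permutations) used Python 3.11.15, numpy 2.4.6, pandas 2.3.3 and scipy 1.17.1, and figures matplotlib 3.10.9.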

Results

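Gene expression was measured in mammary gland, liver and adipose tissue of rats in pregnancy and in lactation, at standard gravity and in hypergravity, a load above that of Earth. Each of these 12 groups held 5 arrays, and per the array codes the same 20 rats gave all 3 tissues. Array codes give the tissue (M, L or A), the rat and the gravity (S or H), and rats with 3 digits were lactating. A separate set of 12 arrays held mammary gland of pregnant rats in 3 groups of 4, namely microgravity (FLT, flight), a flight control (FDS) and a vivarium control (VIV). The number of arrays per group limits the precision of every value. Detection calls were not used here, so folds against means under the array medians (4.32 to 4.56, and 4.87 to 5.02 in the latter set) are approximate. Positions are on the GRCr8 rat assembly, with Entrez gene identifiers, and a gene is described by its brightest probe set.

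Marker genes separated the 3 tissues in all arrays but M210H and A210H. Mammary array M210H had a mean of 3.45 log2 units over the 8 milk protein genes, where the other 4 arrays of its group lay between 11.1 and 11.33. Its mean over 18 adipocyte genes was 10.48, where the others lay between 7.49 and 8.08. Adipose array A210H had 11.28 for milk protein genes against 3.23 to 3.54 in its group, and 7.79 for adipocyte genes against 10.08 to 10.68. Both arrays were kept in their labelled groups, and counts, and most calls that changed, are also given without them. Skeletal muscle marker means lay over 2 log2 units above the median of their tissue and set in M212H (3.61 above), M50H (3.83), VIVA (3.35), VIVC (3.61), A48S (7.78), A217H (6.48) and A210H (3.44). Hepatocyte marker means did so in M56H (6.69), M52S (3.47) and M57S (2.03). Counts without all of these arrays are called counts without arrays carrying markers of another tissue. Both of these repeats were chosen after seeing the data.

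**Figure D1:**
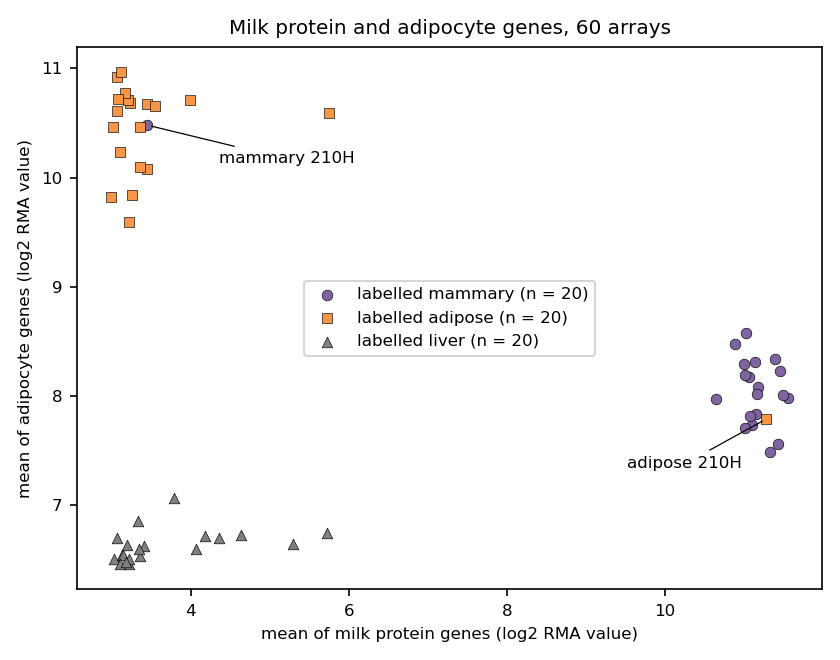
Mean log2 signal of 8 milk protein genes (x axis) against that of 18 adipocyte genes (y axis) for the 60 arrays of the standard gravity and hypergravity groups, 1 point per array, by labelled tissue. The mammary-labelled M210H (3.45, 10.48) lies among the adipose arrays and the adipose-labelled A210H (11.28, 7.79) among the mammary arrays.

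The change of the mammary gland from pregnancy to lactation was measured first at standard gravity (n = 5 per group). Atp2b2, the plasma membrane calcium pump that moves calcium into milk (gene 24215, chromosome 4, 148450207 to 148763653), was higher in lactation (11.37 ± 0.20 against 2.89 ± 0.37 log2 units, the latter under the array medians, log2 fold change 8.48, SE 0.65, adjusted p = 1e-07). Cidea, a lipid droplet protein of milk fat secretion (gene 291541, chromosome 18, 63164817 to 63190384), was 74.3-fold higher (12.54 ± 0.13 against 6.32 ± 0.69, SE 0.44, adjusted p = 4.6e-08). Rspo1, a secreted enhancer of Wnt signalling (gene 313589, chromosome 5, 142536162 to 142557611), was 69.9-fold lower (3.25 ± 0.16 against 9.38 ± 0.37, SE 0.58, adjusted p = 1.2e-06). Lao1 (78.2-fold), Prkaa2, a catalytic subunit of the energy sensor AMPK (33.3-fold), Folr1, a folate receptor (26.8-fold), and Ddah1, which degrades methylated arginine (26.7-fold), were also higher. Adh1c, an alcohol dehydrogenase (54.5-fold), Mlana (52.3-fold), Card14 (48.8-fold), Ubd, a ubiquitin-like modifier (46.9-fold), and Scara3 (31.8-fold), were lower. For these 12 genes every array of 1 stage lay above every array of the other, with adjusted p of at most 0.0084.

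Of 19 cholesterol synthesis genes 13 rose and 0 fell (15 rose adjusted over the list alone), and the list rose against other genes (adjusted p = 2e-11, and adjusted p = 0.038 with an estimated correlation, but 0.072 without M210H and A210H). Insig1, a regulator of sterol synthesis, rose 14.5-fold (12.37 ± 0.14 against 8.51 ± 0.91, SE 0.58, adjusted p = 8.4e-05), Cyp51, a sterol demethylase, 13.6-fold, and Idi1, an isomerase of isoprenoid synthesis, 13.3-fold. Of 33 cell cycle genes 23 rose and 1 fell. The list had an adjusted p = 1.2e-11, but adjusted p = 0.54 with an estimated correlation. Among its members were Ube2c of the mitotic ubiquitin ligase (5.91-fold), cyclin Ccnb1 (5.24-fold) and topoisomerase Top2a (10.64 ± 0.60 against 8.13 ± 0.34). Of 19 fatty acid synthesis genes 10 rose and 2 fell (list adjusted p = 0.0015, but adjusted p = 0.54 with an estimated correlation), with the desaturase Fads2 up 4.74-fold. Of 22 genes of fatty acid oxidation and ketogenesis 0 rose and 10 fell (list adjusted p = 0.0079, but adjusted p = 0.73 with an estimated correlation). The mitochondrial thiolase Acaa2 fell 10.6-fold, the lipase inhibitor Angptl4 10.2-fold and the carnitine transferase Cpt1a 6.76-fold (7.12 ± 0.16 against 9.88 ± 0.83).

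Of 13 interferon response genes 0 rose and 8 fell (9 adjusted over the list alone), and of 15 macrophage markers 0 rose and 7 fell. Both lists had an adjusted p = 0.0079, and both an adjusted p = 0.73 with an estimated correlation. Irf7, the transcription factor that drives interferon production (gene 293624, chromosome 1, 205796956 to 205800543), fell 12.4-fold (5.45 ± 0.33 against 9.09 ± 0.39, log2 fold change -3.63, SE 0.44, adjusted p = 1.2e-05). Ifit2 fell 6.75-fold, the macrophage lysozyme Lyz2 5.73-fold and the endotoxin receptor Cd14 4.47-fold. Of 8 milk protein genes 0 were called (list adjusted p = 0.67), and most were near the top of the scale in both stages. Beta-casein Csn2 (gene 29173, chromosome 14, 20601824 to 20609061) was 12.93 ± 0.11 in lactation and 12.85 ± 0.11 in pregnancy, Wap 13.57 ± 0.06 and 13.30 ± 0.13, and alpha-lactalbumin Lalba (gene 24528, chromosome 7, 131504572 to 131520707) 13.41 ± 0.04 and 11.89 ± 0.77. The mean of the milk protein list was higher in lactation by 0.42 log2 units (SE 0.04). With M210H and A210H left out, Lalba (log2 fold change 1.52, adjusted p = 0.00041), Wap (0.26, adjusted p = 0.036) and Lpo (1.43, adjusted p = 0.011) were called.

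The clock list was not called against other genes (adjusted p = 0.73), with 4 of 20 members higher and 6 lower. The activators Npas2 (log2 fold change 2.77, SE 0.52, adjusted p = 0.00057), Bmal1 (2.05, SE 0.33, adjusted p = 0.00015) and Clock (0.97, SE 0.14, adjusted p = 5.3e-05) were higher in lactation. The output regulator Dbp (-2.0, SE 0.52, adjusted p = 0.0066) and the repressors Per1 (-0.88, SE 0.22, adjusted p = 0.0046) and Nr1d1 (-1.71, SE 0.53, adjusted p = 0.019) were lower. The labels give no time of day. Of 13 luminal epithelium markers 0 rose and 4 fell (list adjusted p = 0.47), namely Prom1 (7.60-fold), Krt8 (3.24-fold), Krt19 and Krt18. Without M210H and A210H 8 fell, with list adjusted p = 0.024, but adjusted p = 0.50 with an estimated correlation. The prolactin receptor Prlr was not called (8.69 ± 0.47 against 6.91 ± 0.90, adjusted p = 0.0504), and was called without M210H and A210H (adjusted p = 0.014) or without M42S alone (adjusted p = 0.023). Elf5, a regulator of alveolar cells, was 10.83 ± 0.21 and 10.65 ± 0.40 (adjusted p = 0.93).

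Over all probe sets limma called 9614, with 4779 higher and 4835 lower in lactation. The count was 10581 without M210H and A210H and 8886 without arrays carrying markers of another tissue. Leaving out 1 array ended the call of 5 of the 55 called genes that were named by rule, among them Krt19 (adjusted p = 0.052 without M52S), Krt18 (0.088 without M42S) and Nr1d1 (0.06 without M44S).

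**Figure D2:**
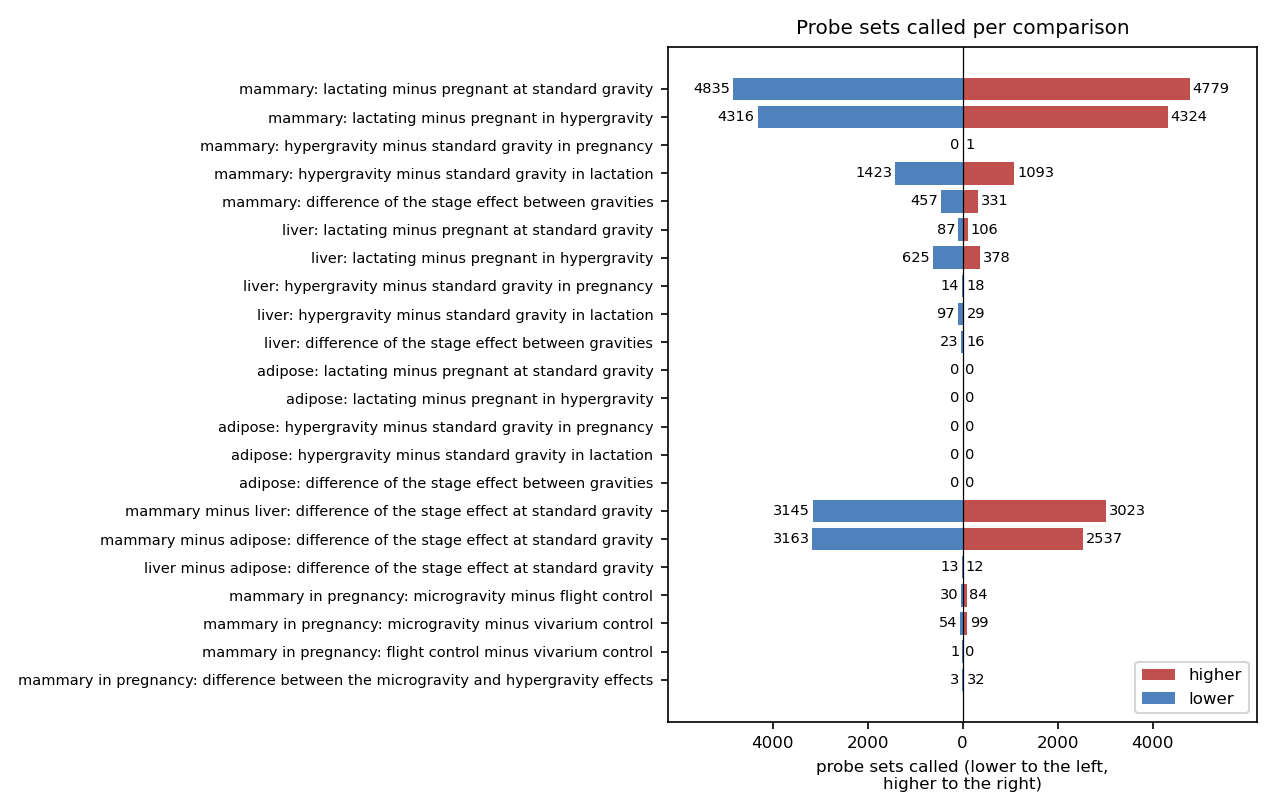
Number of probe sets called (adjusted p under 0.05, limma) higher (red, right) and lower (blue, left) in each comparison, on a linear axis. The stage contrasts of the mammary gland reach 4779 higher and 4835 lower, and the 5 adipose contrasts stay at 0.

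The stage effect in hypergravity was measured the same way, and the lactating group here holds M210H with adipocyte markers and M212H with muscle markers. Wfdc18, a protease inhibitor homologue, was 33.1-fold higher in lactation (8.36 ± 2.21 against 3.32 ± 0.25, n = 5 per group, SE 0.67, adjusted p = 5.5e-05). The inflammatory calcium-binding protein S100a8 was 29.8-fold higher and the bicarbonate transporter Slc4a4 20.8-fold higher (9.55 ± 0.45 against 5.17 ± 0.95). Wfdc10a was 33.3-fold lower, Rspo1 24.9-fold lower and Moxd1 19.8-fold lower. Of 33 cell cycle genes 0 rose and 16 fell with lactation (list adjusted p = 0.00053, but 0.11 without arrays carrying markers of another tissue and adjusted p = 0.98 with an estimated correlation), led by cyclin Ccna2 (3.73 ± 0.77 against 6.21 ± 0.69, log2 fold change -2.49, SE 0.48, adjusted p = 0.00098). Of 17 fibroblast and matrix genes 8 rose and 0 fell (list adjusted p = 0.00051, but adjusted p = 0.98 with an estimated correlation). Without M210H and A210H 6 rose (list adjusted p = 0.0079). The collagen crosslinker Lox rose 6.07-fold, the protease inhibitor Timp1 5.52-fold and Col1a1 1.94-fold.

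Of the interferon genes 0 rose and 5 fell in hypergravity (list adjusted p = 0.24), with Irf7 at -2.55 (SE 0.44, adjusted p = 0.00041). Milk protein genes had 0 calls (list adjusted p = 0.87). Lalba was at -0.70 (SE 1.36, adjusted p = 0.75) with all arrays and at 1.34 (adjusted p = 0.0026), a reversed direction, without M210H and A210H. Csn2 was at -1.98 and Wap at -2.0 (adjusted p = 0.29 and 0.28), and without M210H and A210H at 0.03 and -0.01 (adjusted p = 0.86 and 0.95). Of 20 clock genes 2 rose and 3 fell (list adjusted p = 0.96), with Bmal1 at 1.02 (SE 0.33, adjusted p = 0.025, and 0.077 without M212H), Nr1d1 at -1.84 (SE 0.53, adjusted p = 0.014) and Clock at 0.14 (adjusted p = 0.51). In all limma called 8640 probe sets (4324 higher, 4316 lower), but 5479 with only the groups compared. The count was 9080 without M210H and A210H and 9002 without arrays carrying markers of another tissue. Besides Bmal1, the calls of Bhlhe41 (adjusted p = 0.089 without M203H), Col5a1 (0.051 without M212H) and Per1 (0.086 without M55H) ended without 1 array. Calls at both gravities were shared in the same direction by 5470 probe sets (2672 higher and 2798 lower, where chance gives 666 and 672) and 128 were opposite. Across probe sets, which are not independent replicates, the log2 fold changes of the 2 stage contrasts correlated at r = 0.74.

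Hypergravity was compared with standard gravity within pregnancy in the mammary gland (n = 5 per group). The gene called was Mmp9, a gelatinase that degrades matrix (gene 81687, chromosome 3, 174103474 to 174111434), which was 5.80-fold higher in hypergravity (5.61 ± 1.07 against 3.07 ± 0.18, log2 fold change 2.54, SE 0.36, adjusted p = 0.034). Of 17 fibroblast and matrix genes 0 were called over all probe sets and 5 fell adjusted over the list alone, and the list fell against other genes (adjusted p = 7.8e-11, but adjusted p = 0.44 with an estimated correlation). Col1a1 was at -0.91 (SE 0.22, adjusted p = 0.65). The lists of fatty acid synthesis (adjusted p = 0.0038), interferon response (0.0069), clock genes (0.01) and endothelium (0.046) lay lower and that of lymphocyte markers higher (0.01), with adjusted p of 0.45 to 0.62 with an estimated correlation. Calls ended without 1 array for interferon response and endothelium (0.21 and 0.18 without M56H), clock genes (0.099 without M50H) and lymphocyte markers (0.42 without M60H). Without arrays carrying markers of another tissue those of fatty acid synthesis (0.052), interferon response (0.18), clock genes (0.35) and endothelium (0.052) ended. Csn2, Lalba, Wap, Prlr and Elf5 differed by at most 0.11 log2 units (adjusted p = 1). The number of lists called (6) was 10 without M55H or M52S and 11 without M57S.

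In total limma called 1 probe set here, and 1390 had an unadjusted p under 0.05. The count was 0 without any 1 of 15 arrays (M203H, M206H, M212H, M217H, M55H, M59H, M201S, M202S, M214S, M216S, M42S, M44S, M48S, M52S and M57S). It was 2 without M60H, 7 without M56H, which carries hepatocyte markers, and 2 without all arrays carrying markers of another tissue. The adjusted p of Mmp9 reached 0.18 without M48S.

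In lactation hypergravity went with a wide change of the mammary gland (n = 5 per group, with M210H and M212H in the hypergravity group). Atp2b2 was 74.0-fold lower than at standard gravity (5.16 ± 2.15 against 11.37 ± 0.20, log2 fold change -6.21, SE 0.65, adjusted p = 7.8e-06). The mitotic genes Cenpu, Ttk and Nusap1 were 20.7-fold, 16.5-fold and 15.3-fold lower, and Ggt1 was 15.3-fold lower. Pdk4, the kinase that slows pyruvate oxidation, was 24.1-fold higher (9.87 ± 0.64 against 5.28 ± 0.93, log2 fold change 4.59, SE 0.56, adjusted p = 4.1e-05), and Mt2A, a metallothionein, 20.8-fold higher (12.29 ± 0.61 against 7.91 ± 1.25). Wfdc18 (36.6-fold), Slc4a4 (23.5-fold), Angptl4 (12-fold) and the galectin Lgals3 (11.7-fold) were higher as well.

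Cell cycle genes fell as a group, with 30 of 33 called lower and 0 higher (list adjusted p = 4.9e-35, and adjusted p = 0.024 with an estimated correlation). Cyclin Ccna2 fell 14.5-fold (3.73 ± 0.77 against 7.59 ± 1.05, log2 fold change -3.86, SE 0.48, adjusted p = 4.6e-05) and Top2a 12.6-fold (6.98 ± 1.55 against 10.64 ± 0.60). With M210H and A210H left out 29 of them were called lower (adjusted p = 0.037 with an estimated correlation). Of 19 cholesterol synthesis genes 9 fell and 0 rose (list adjusted p = 3e-12, and adjusted p = 0.024 with an estimated correlation), Idi1 4.95-fold (6.58 ± 0.57 against 8.89 ± 0.18) and the decarboxylase Mvd 3.98-fold. Of 19 fatty acid synthesis genes 11 fell and 0 rose (list adjusted p = 9.9e-10, and adjusted p = 0.025 with an estimated correlation). The desaturase Scd (gene 246074, chromosome 1, 253218968 to 253232101) fell 16.4-fold (7.11 ± 2.35 against 11.14 ± 0.12, SE 1.01, adjusted p = 0.017, and 0.054 without M206H), Fads2 12.1-fold and the carboxylase Acaca 7.40-fold.

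With all arrays, 4 lists lay higher at the preset correlation but were not called with an estimated one. Of 22 fatty acid oxidation genes 8 rose (list adjusted p = 2.9e-06, but adjusted p = 0.18 with an estimated correlation), among them Cpt1a (7.20-fold) and Acaa2 (6.77-fold). Of 15 macrophage markers 5 rose (list adjusted p = 2.9e-06, but adjusted p = 0.095 with an estimated correlation), led by Cd14 (8.88-fold, 11.28 ± 0.85 against 8.13 ± 0.90). Of 14 genes of involution (the regression of the gland after weaning) and Stat3 signalling 5 rose (list adjusted p = 2.5e-05, but adjusted p = 0.11 with an estimated correlation), with Stat3 up 3.51-fold. Without M210H and A210H 8 involution genes were called (adjusted p = 0.045 with an estimated correlation). Of 17 fibroblast and matrix genes 2 rose (list adjusted p = 0.0068, but 0.053 without M210H and A210H, and adjusted p = 0.67 with an estimated correlation). The milk fat secretion list fell (adjusted p = 0.0085, but adjusted p = 0.18 with an estimated correlation), with 1 of 14 higher and 4 lower, among the latter Fabp3 (6.18-fold), Gpat4 (5.09-fold) and Cidea (4.47-fold). Oxidative phosphorylation genes had 0 of 24 called (list adjusted p = 0.014, lower, but 0.076 without M203H and adjusted p = 0.67 with an estimated correlation).

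Of 13 luminal epithelium markers 2 were higher with all arrays (list adjusted p = 0.28), Krt7 10.1-fold and Krt19 5.55-fold (adjusted p = 0.042, and 0.097 without M216S). Without M210H and A210H 8 were higher (adjusted p = 0.037 with an estimated correlation). Milk protein genes had 1 higher and 1 lower (list adjusted p = 0.11), the peroxidase Lpo at -2.89 (SE 0.68, adjusted p = 0.011) and Spp1 at 1.15 (SE 0.30, adjusted p = 0.02, and 0.062 without M203H). Csn2 was 10.84 ± 4.51 against 12.93 ± 0.11 (adjusted p = 0.45), Lalba 11.25 ± 4.56 against 13.41 ± 0.04 (adjusted p = 0.45) and Wap 11.24 ± 4.45 against 13.57 ± 0.06 (adjusted p = 0.37), with M210H far below the other 4 arrays. With M210H and A210H left out the log2 fold changes were -0.08 for Csn2, -0.11 for Lalba and -0.34 for Wap, of which Wap was called (adjusted p = 0.037). Prlr was at -1.92 (SE 0.67, adjusted p = 0.092) and Elf5 at -2.24 (SE 0.99, adjusted p = 0.21), and without M210H and A210H at -1.28 and -0.78 (adjusted p = 0.20 and 0.078). The clock list was not called (adjusted p = 0.052), with 1 higher and 4 lower, among the latter Cry1 at -2.22 (SE 0.41, adjusted p = 0.0017).

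Of all probe sets limma called 2516 (1093 higher, 1423 lower), 2928 without M210H and A210H and 2769 without arrays carrying markers of another tissue. Other calls of named genes that ended without 1 array were Bhlhe41 (adjusted p = 0.061 without M201S), C1qb (0.12 without M216S) and Slc27a1 (0.11 without M216S).

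Whether the stage effect differed between gravities was tested directly in the mammary gland, as the effect of lactation in hypergravity minus that at standard gravity. Atp2b2 differed by -6.26 log2 units (SE 0.92, n = 5 in each of the 4 groups, adjusted p = 0.001), with 5.16 ± 2.15 in lactation and 2.94 ± 0.21 in pregnancy in hypergravity. Slc4a4 differed by 5.31 (SE 0.64, adjusted p = 0.00021), Pdk4 by 5.18 (SE 0.79, adjusted p = 0.0014) and Cenpu by -4.72 (SE 0.55, adjusted p = 0.00014). In 24 of 33 cell cycle genes the difference was called negative and in 0 positive (list adjusted p = 4e-35). It was negative in 5 of 19 cholesterol synthesis genes (list adjusted p = 4.1e-11), and both lists had adjusted p = 0.024 with an estimated correlation, and 0.051 without M210H and A210H. It was negative too in 3 of 19 fatty acid synthesis genes (list adjusted p = 2.1e-05, but adjusted p = 0.13 with an estimated correlation). Examples are Ccna2 at -4.18 (SE 0.68, adjusted p = 0.0021) and Mvd at -2.29 (SE 0.25, adjusted p = 8.8e-05).

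The difference was called positive in 3 of 17 fibroblast and matrix genes (list adjusted p = 2.6e-08), 6 of 22 fatty acid oxidation genes (1.4e-07), 3 of 15 macrophage markers (1.9e-06) and 3 of 14 involution genes (0.0002). With an estimated correlation these 4 lists had adjusted p = 0.15, 0.13, 0.11 and 0.15. Timp1 differed by 2.48 (SE 0.44, adjusted p = 0.0043) and Cd14 by 3.72 (SE 0.66, adjusted p = 0.0041). Csn2, Lalba, Wap, Prlr and Elf5 were not called, with adjusted p of at least 0.36. Over all probe sets limma called 788 (331 positive, 457 negative), 915 without arrays carrying markers of another tissue, 1250 without M210H and A210H and 515 without M44S. The calls of Mrc1 (adjusted p = 0.093 without M59H) and Postn (0.093 without M52S) ended without 1 array.

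**Figure D3:**
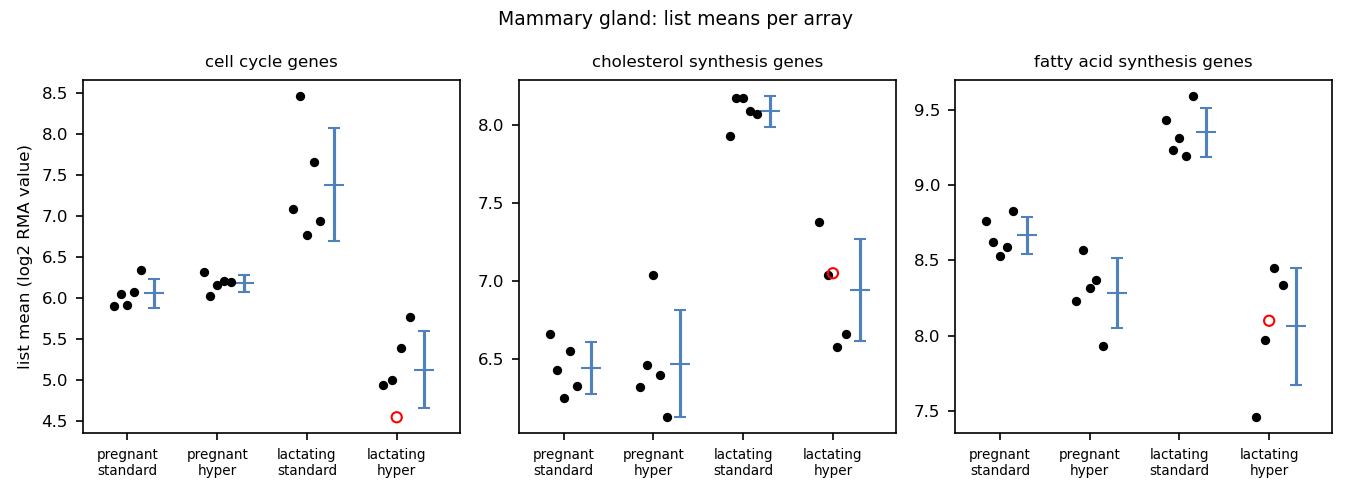
Mean log2 signal of 33 cell cycle, 19 cholesterol synthesis and 19 fatty acid synthesis genes per mammary array (black points, with M210H as an open red circle), with mean ± SD of each group of 5 (blue, M210H included). In lactation the cell cycle mean ran from 6.77 to 8.46 at standard gravity and from 4.54 to 5.76 in hypergravity.

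In the liver the stage contrast at standard gravity (n = 5 per group) was led by lower interferon response genes. Irf7 was 4.73-fold lower in lactation (5.46 ± 0.36 against 7.70 ± 0.27, log2 fold change -2.24, SE 0.18, adjusted p = 2.5e-06), Usp18, which trims the ubiquitin-like Isg15, 4.84-fold lower, and the antiviral genes Oas1a and Mx1 4.64-fold and 4.13-fold lower. Of 13 interferon response genes 7 fell and 0 rose (list adjusted p = 6.3e-16, and adjusted p = 0.00092 with an estimated correlation). The phosphate transporter Slc34a2 was 9.80-fold higher (7.34 ± 1.44 against 4.04 ± 0.78, SE 0.61, adjusted p = 0.013), Sez6 5.92-fold, Acsm2, an acyl-CoA synthetase, 4.86-fold, Arhgap33 4.20-fold, Popdc2 3.69-fold and Atp2b2 3.40-fold. Tsx was 5.69-fold lower, Prlr 2.16-fold lower (9.62 ± 0.29 against 10.74 ± 0.47) and the growth hormone receptor Ghr 1.49-fold lower (adjusted p = 0.014).

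Of 11 immediate early genes 3 fell and 0 rose (list adjusted p = 2e-05, but adjusted p = 0.13 with an estimated correlation), Fos 4.57-fold, Egr1 2.49-fold and Junb 1.98-fold. The lists of heat shock genes (list adjusted p = 2e-05), bile acid transport (0.0076) and actin and adhesion genes (0.012) lay higher, with 0 members called, and adjusted p = 0.16, 0.13 and 0.27 with an estimated correlation. Those of glucocorticoid response (0.0014), cell cycle (0.006, 1 gene called), fatty acid oxidation (0.012) and gluconeogenesis (0.012) lay lower, with adjusted p = 0.13, 0.57, 0.57 and 0.27 with an estimated correlation. Without 1 array the calls of actin and adhesion (0.16 without L216S), fatty acid oxidation (0.10 without L48S) and gluconeogenesis lists (0.098 without L57S) ended. Bmal1, Clock, Per1, Per2, Nr1d1 and Dbp were not called (adjusted p of at least 0.13).

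Limma called 193 probe sets in this contrast (106 higher, 87 lower). The count was 106 without L52S, 107 without L214S, 111 without L201S, 115 without L48S, 117 without L42S, 119 without L216S, 124 without L44S, 127 without L219S, 315 without L212H and 323 without L57S. Calls that ended without 1 array were those of Atp2b2 (adjusted p = 0.054 without L201S), Egr1 (0.064 without L42S), Popdc2 (0.074 without L48S) and Prlr (0.056 without L52S). Of the probe sets called in mammary gland and liver, 47 moved in the same direction (22 higher and 25 lower, where chance gives 16.3 and 13.6) and 29 in opposite directions (chance 29.9). Chance here takes the tissues as independent, although by code they share rats. That shared number was 29 without L201S, 31 without L42S, 73 without L57S and 78 without L212H.

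The stage contrast of the liver in hypergravity followed (n = 5 per group). Lifr, the receptor of leukemia inhibitory factor (gene 81680, chromosome 2, 57951787 to 58020357), was 24.2-fold lower (5.18 ± 0.83 against 9.78 ± 0.17, log2 fold change -4.60, SE 0.33, adjusted p = 1.4e-07). Scd was 11.6-fold lower (6.85 ± 0.61 against 10.39 ± 0.70) and Fads2 9.16-fold lower. Higher were Gpt, an alanine transaminase (8.03-fold, 9.08 ± 0.55 against 6.07 ± 0.74), the retinol carrier Rbp7 (7.90-fold) and serine dehydratase Sds (7.33-fold). Of 19 cholesterol synthesis genes 12 fell and 0 rose (list adjusted p = 7.2e-16, but adjusted p = 0.09 with an estimated correlation), with squalene epoxidase Sqle down 4.56-fold. Of 19 fatty acid synthesis genes 9 fell and 0 rose (list adjusted p = 4.7e-13, but adjusted p = 0.053 with an estimated correlation). Fatty acid synthase Fasn (gene 50671, chromosome 10, 106570415 to 106588581) fell 5.17-fold (7.87 ± 1.07 against 10.24 ± 0.11).

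Of 13 interferon genes 6 fell and 0 rose (list adjusted p = 6e-09, and adjusted p = 0.021 with an estimated correlation), with Mx1 down 4.42-fold and Ifit3 2.49-fold. Of 10 gluconeogenesis genes 4 rose (list adjusted p = 0.00092, but adjusted p = 0.11 with an estimated correlation), Gpt, Sds, Got1 (2.07-fold) and the glucose 6-phosphate carrier Slc37a4 (1.75-fold). Lists of oxidative phosphorylation (0 of 24 called, list adjusted p = 5.9e-06), cell cycle (2 called, 0.00058) and bile acid transport (1 called, 0.0029) lay higher and that of the unfolded protein response (2 called, 6.5e-05) lower. With an estimated correlation they had adjusted p = 0.27, 0.61, 0.076 and 0.27, and the cell cycle call ended without L203H (0.12). Bmal1, Clock, Per1, Per2, Nr1d1 and Dbp were not called, with adjusted p of at least 0.49. In this contrast limma called 1003 probe sets (378 higher, 625 lower), 639 without L50H and 596 with only the groups compared. Without L50H the calls of Idi1 (adjusted p = 0.079) and Lss (0.057) ended, and without L56H that of Got1 (0.092). Of these calls 73 were shared in direction with the contrast at standard gravity (24 higher and 49 lower, where chance gives 1.29 and 1.75) and 0 were opposite, and the number was 125 without L57S.

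Within pregnancy, hypergravity changed few liver genes (n = 5 per group). Tbx3, a T-box transcription factor, was 2.79-fold higher than at standard gravity (10.62 ± 0.18 against 9.14 ± 0.37, log2 fold change 1.48, SE 0.16, adjusted p = 0.00031), and the somatostatin receptor Sstr1 was 4.37-fold higher (5.54 ± 0.61 against 3.41 ± 0.55, adjusted p = 0.014). Atp2b2 (3.80-fold), the ephrin receptor Epha4 (3.57-fold), Svil (2.75-fold) and Slc25a45 (2.46-fold) were higher. Pfkfb1, a regulator of glycolysis (4.11-fold), the lipid transporter Mfsd2a (3.65-fold), Scd2 (3.28-fold), Wfdc21 (3.24-fold), Got1 (2.67-fold) and Nmrk1 (2.24-fold) were lower. The gluconeogenesis list fell (1 of 10 called, 4 adjusted over the list alone, list adjusted p = 9.4e-06, but adjusted p = 0.064 with an estimated correlation). Lists of immediate early genes (list adjusted p = 1.2e-05), cell cycle (0.00013), clock genes (0.0011) and fatty acid synthesis (0.0035) lay lower and the unfolded protein response higher (0.0011), with adjusted p of 0.14 to 0.51 with an estimated correlation, and the call of fatty acid synthesis ended without L42S (0.052).

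For this comparison limma called 32 probe sets (18 higher, 14 lower), and 2507 had an unadjusted p under 0.05. The count was 6 without L50H, 6 without L48S, 10 without L56H, 20 without L44S and 51 without L216S. Of the 12 called genes named by rule, 10 lost their call without 1 array, all but Sstr1 and Tbx3, with adjusted p up to 0.15 for Got1 and Nmrk1 without L56H.

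In the lactating liver, fatty acid synthesis genes were lower in hypergravity (n = 5 per group). Scd was 9.23-fold lower (6.85 ± 0.61 against 10.06 ± 1.67, SE 0.56, adjusted p = 0.014), Lifr 7.67-fold lower (5.18 ± 0.83 against 8.12 ± 0.69, SE 0.33, adjusted p = 0.00025) and Fasn 6.49-fold lower (7.87 ± 1.07 against 10.57 ± 0.42, SE 0.35, adjusted p = 0.0013). Otub2 and Paqr9 were 3.26-fold and 3.11-fold lower, and Cimap1b was 3.18-fold higher. Of 19 fatty acid synthesis genes 7 fell and 0 rose (list adjusted p = 1e-19, and adjusted p = 0.019 with an estimated correlation). Of 19 cholesterol synthesis genes 10 fell and 0 rose (list adjusted p = 5.6e-22, but adjusted p = 0.061 with an estimated correlation), with Sqle down 5.31-fold and Idi1 3.68-fold. Lists of oxidative phosphorylation (list adjusted p = 1.6e-07), cell cycle (0.00066) and gluconeogenesis (0.016) lay higher and that of heat shock genes lower (0.014), with 0 members called over all probe sets. With an estimated correlation they had adjusted p = 0.33, 0.66, 0.39 and 0.66. The calls of cell cycle (0.17 without L203H), gluconeogenesis (0.076 without L214S) and heat shock lists (0.095 without L217H) ended without 1 array.

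**Figure D4:**
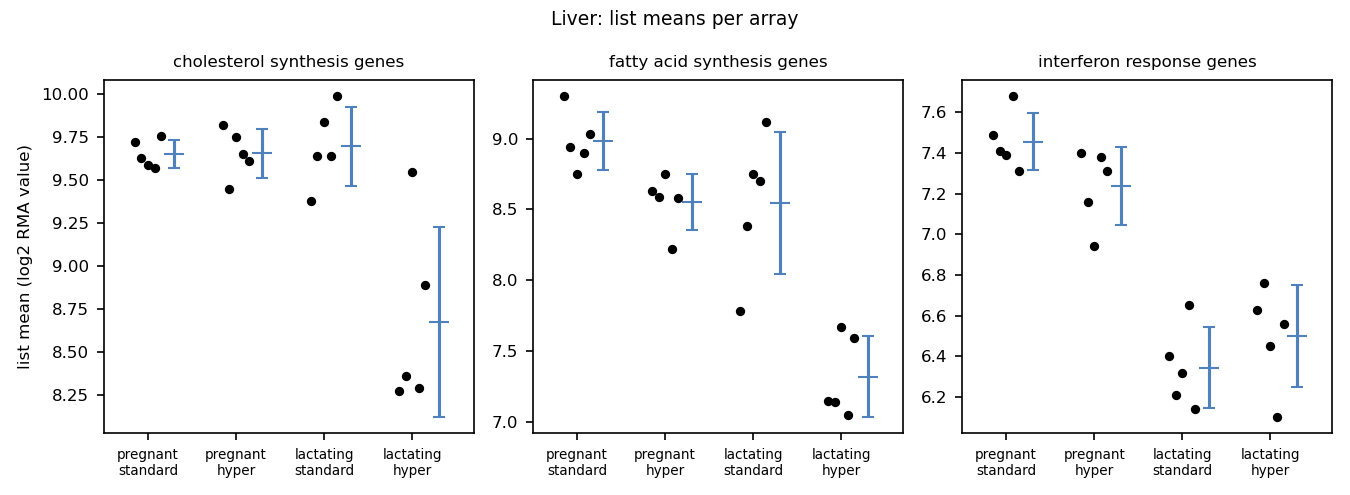
Mean log2 signal of 19 cholesterol synthesis, 19 fatty acid synthesis and 13 interferon response genes per liver array (black points), with mean ± SD of each group of 5 (blue). The lipid synthesis means are lowest in lactation in hypergravity, and the interferon means are lower in both lactating groups than in both pregnant groups.

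Here limma called 126 probe sets (29 higher, 97 lower), but 1 with only the groups compared, where all 18 calls of genes named by rule ended (Lifr at adjusted p = 0.059). The count was 34 without L219S, 47 without L203H, 50 without L212H, 64 without L202S, 67 without L201S, 68 without L216S, 78 without L60H and 244 without L210H. Without 1 array 11 of the 18 calls ended, with adjusted p up to 0.12 for C10h16orf90 without L203H, and those of Cimap1b, Scd, Lifr, Fasn, Otub2, Paqr9 and Fdps stayed under 0.05. In hypergravity against standard gravity in lactation, 32 probe sets were called in the same direction in mammary gland and liver (2 higher and 30 lower, where chance gives 1.02 and 4.45 if the tissues, which by code share rats, were independent) and 6 in opposite directions (chance 4.74). That shared number was 0 when each fit held only the groups compared and 21 with quantile normalization applied again. Leaving out 1 liver array gave 7 (L219S), 10 (L212H), 12 (L203H), 14 (L202S), 16 (L216S), 17 (L214S), 17 (L60H), 18 (L201S), 18 (L50H) or 49 (L210H).

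The stage effect in the liver differed between gravities for a small set of genes (n = 5 in each of the 4 groups). The difference was -3.35 log2 units for Lifr (SE 0.47, adjusted p = 0.0047), -2.97 for Sstr1 (SE 0.43, adjusted p = 0.0061), 4.84 for Sds (SE 0.81, adjusted p = 0.026) and 3.28 for Fos (SE 0.59, adjusted p = 0.032). Of 10 gluconeogenesis genes 2 were called positive (list adjusted p = 7.6e-07, and adjusted p = 0.046 with an estimated correlation), Sds and Got1 (2.10, SE 0.37, adjusted p = 0.031). Of 19 fatty acid synthesis genes 2 were called negative (list adjusted p = 7.1e-08), Fasn (-2.57, SE 0.49, adjusted p = 0.04) and Thrsp, a lipogenic regulator (-1.0, SE 0.19, adjusted p = 0.04). Of 19 cholesterol synthesis genes 0 were called over all probe sets and 13 were negative adjusted over the list alone (list adjusted p = 5.7e-16). With an estimated correlation the latter pair of lists had adjusted p = 0.18. Cell cycle (list adjusted p = 1.6e-07), oxidative phosphorylation (0.00022) and immediate early genes (0.00055) were positive and the unfolded protein response (0.00021) and heat shock genes (0.00055) negative, with adjusted p of 0.33 to 0.37 with an estimated correlation.

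Limma called 39 such differences (16 positive, 23 negative). The count was 10 without L48S, 12 without L214S, L60H or L57S, 16 without L59H, 17 without L216S, 20 without L52S, 21 without L202S, 22 without L219S, 23 without L203H or L201S and 119 without L210H. Of the 9 named calls those of Lifr and Sstr1 alone stayed under 0.05 in every repeat without 1 array, and the highest adjusted p was 0.093 for Fasn without L48S.

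Adipose tissue gave 0 calls by limma in each of the 5 contrasts (n = 5 per group). The smallest adjusted p were 0.051, 0.35, 1, 1 and 0.99 for the stage effect at standard gravity and in hypergravity, for hypergravity in pregnancy and in lactation, and for the difference of stage effects. In the same order 1533, 1500, 1047, 1090 and 1226 probe sets had an unadjusted p under 0.05. Hsph1, a heat shock chaperone (gene 288444, chromosome 12, 10427368 to 10446602), came nearest, at 11.76 ± 0.31 in lactation and 10.64 ± 0.18 in pregnancy at standard gravity (log2 fold change 1.12, SE 0.16, adjusted p = 0.051). It was called without M210H and A210H (adjusted p = 0.04), and the count was also 1 without any 1 of A210H, A219S, A50H and A48S. The heat shock list rose (2 of 7 adjusted over the list alone, list adjusted p = 1.3e-06, and adjusted p = 0.048 with an estimated correlation, but 0.051 without M210H and A210H). At that gravity the interferon list fell (4 of 13 adjusted over the list alone, list adjusted p = 4e-07, but adjusted p = 0.68 with an estimated correlation), with Mx2 at -2.70 (SE 0.75, adjusted p = 0.93).

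In hypergravity the interferon list fell with lactation (5 of 13 adjusted over the list alone, list adjusted p = 7.7e-07, but adjusted p = 0.54 with an estimated correlation), with Oas1a at -1.17 (SE 0.34, adjusted p = 1). The lists of fatty acid synthesis (0.00014), skeletal muscle (0.00024) and milk proteins (0.0022) lay higher (adjusted p = 0.55 with an estimated correlation for each), and the lactating hypergravity group holds A210H with milk protein markers and A217H with muscle markers. The milk protein list was not called without M210H and A210H (adjusted p = 0.69), nor the muscle list without A217H (0.12). Hypergravity against standard gravity in lactation gave higher fatty acid synthesis genes (2 of 19 adjusted over the list alone, list adjusted p = 1.3e-05), with Fasn at 11.67 ± 0.23 against 10.11 ± 0.81 (adjusted p = 1), and lower macrophage markers (list adjusted p = 1.4e-06). Both lists had adjusted p = 0.46 with an estimated correlation. In pregnancy the fibroblast and matrix list was lower in hypergravity (2 of 17 adjusted over the list alone, list adjusted p = 1.5e-05, but adjusted p = 0.78 with an estimated correlation), with Postn at -0.95 (SE 0.28, adjusted p = 1). In the order above 7, 15, 6, 12 and 10 of 33 lists were called, and 1, 0, 0, 0 and 0 with an estimated correlation. The number was 12 without A202S for stage at standard gravity and 9 without A206H or A56H for stage in hypergravity.

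The stage effects at standard gravity were compared between tissues by a direct test (n = 5 per group and tissue). Atp2b2 rose more in the mammary gland than in liver by 6.72 log2 units (SE 1.04, adjusted p = 4.2e-06), and the difference from adipose tissue was 8.96 (SE 1.04, adjusted p = 1.9e-08). Lao1 exceeded liver by 6.37 and adipose tissue by 6.49 (SE 1.06 for both), and Ccn3, a matricellular protein, exceeded liver by 6.17 (SE 0.69). Rspo1 (-5.83 and -6.44, SE 0.71), Mlana (-5.59 and -5.81, SE 0.60), Adh1c (-5.64 against liver) and Card14 (-6.50 against adipose tissue) went the other way. The difference was positive in 12 of 19 cholesterol synthesis genes against liver (list adjusted p = 3.2e-09) and in 12 against adipose tissue (list adjusted p = 8.7e-10), but adjusted p = 0.20 and 0.33 with an estimated correlation. It was positive in 22 of 33 cell cycle genes against liver (list adjusted p = 8.2e-14) and in 13 with 1 negative against adipose tissue (8.7e-10), but adjusted p = 0.20 and 0.56 with an estimated correlation.

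Fatty acid synthesis genes were positive in 9 and negative in 1 of 19 against liver (list adjusted p = 0.0018, but adjusted p = 0.96 with an estimated correlation) and positive in 6 against adipose tissue (list adjusted p = 0.0018, but adjusted p = 0.86 with an estimated correlation). Against adipose tissue 9 of 15 macrophage markers (list adjusted p = 0.0003) and 7 of 22 fatty acid oxidation genes (0.004) were negative, with adjusted p = 0.86 and 1 with an estimated correlation, among them Cd14 at -2.95 (SE 0.50, adjusted p = 2.1e-05). Csn2, Lalba, Wap and Elf5 were not called in either contrast (adjusted p of at least 0.64). Prlr was at 2.58 against liver (SE 0.96, adjusted p = 0.0501) and at 2.61 against adipose tissue (SE 0.96, adjusted p = 0.0497, and 0.11 without A52S). In all 6168 probe sets were called against liver (3023 positive, 3145 negative) and 5700 against adipose tissue (2537 positive, 3163 negative). Calls that ended without 1 array were Cry2 (adjusted p = 0.065 without M216S) and Hlf (0.086 without L216S) against liver and Mki67 (0.063 without A202S) against adipose tissue.

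Liver and adipose tissue differed in stage effect for 25 probe sets (12 positive, 13 negative), and 1834 had an unadjusted p under 0.05. Sez6 was at 2.74 (SE 0.39, adjusted p = 0.00014), Acsm2 at 2.34 (SE 0.40, adjusted p = 0.0017), the chemokine Cxcl14 at -2.98 (SE 0.56, adjusted p = 0.0071) and Tsx at -2.39 (SE 0.44, adjusted p = 0.0059). Of 33 lists 6 were called, among them immediate early genes (lower) and skeletal muscle genes (higher), each with list adjusted p = 0.00089, and all 6 had adjusted p = 0.88 with an estimated correlation. The count was 15 without A48S, the array with muscle markers, 15 without L216S, 42 without L57S and 6 with only the groups compared, and 3 lists were called without A48S, the muscle list not among them (adjusted p = 0.93). The calls of Popdc2 (adjusted p = 0.16 without A48S) and Aldh1b1 (0.075 without L216S) ended. With the rat code as a block the 3 tissue contrasts gave 6716, 6293 and 26 calls, and the calls of Prlr in mammary gland against adipose tissue (adjusted p = 0.084) and Popdc2 (0.067) ended.

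Microgravity was compared with the flight control in the mammary gland of pregnant rats (n = 4 per group). Sftpd, the collectin surfactant protein D (gene 25350, chromosome 16, 17080575 to 17093047), was 4.31-fold higher after flight (7.19 ± 0.25 against 5.09 ± 0.38, log2 fold change 2.11, SE 0.19, adjusted p = 0.0022). Fkbp5, a glucocorticoid-induced chaperone of the steroid receptors (gene 361810, chromosome 20, 6458931 to 6577227), was 3.89-fold higher (9.45 ± 0.32 against 7.48 ± 0.51, log2 fold change 1.96, SE 0.23, adjusted p = 0.0048). The tight junction gene Cldn1 (3.60-fold), Fam180a (3.38-fold), the carnitine synthesis enzyme Bbox1 (3.35-fold) and the aquaporin Aqp9 (3.12-fold) were higher. Prnd (2.37-fold), the kinase Fgr (2.16-fold), Banp (2.16-fold), Apol11a (2.04-fold), tubulin Tube1 (1.98-fold) and Nrp2 (1.93-fold) were lower. Of 19 fatty acid synthesis genes 3 rose (6 adjusted over the list alone, list adjusted p = 8e-09, but adjusted p = 0.10 with an estimated correlation), Acaca 1.99-fold, Slc25a1 1.91-fold and Fasn 1.57-fold. Of 9 glucocorticoid response genes 1 rose, Fkbp5 (list adjusted p = 8.7e-06, but adjusted p = 0.13 with an estimated correlation). Of 33 cell cycle genes 1 fell, Kif11 by 1.67-fold (8 adjusted over the list alone, list adjusted p = 1.1e-08, but adjusted p = 0.40 with an estimated correlation).

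The list of milk fat secretion lay higher (9 of 14 adjusted over the list alone, 0 over all probe sets, list adjusted p = 1.2e-05), as did those of luminal epithelium (0.0015, and 0.064 without FDSB), clock genes (0.0028, and 0.076 without FDSA) and milk proteins (0.031, and 0.26 without FDSA). Lymphocyte markers lay lower (0.046, and 0.28 without FDSB). With an estimated correlation they had adjusted p = 0.25, 0.60, 0.40, 0.60 and 0.76. Csn2 (0.12), Lalba (0.44), Wap (0.27), Prlr (-0.21) and Elf5 (0.40) were not called, with adjusted p of at least 0.19. Limma called 114 probe sets (84 higher, 30 lower), 208 with each array centred on its median, 43 with the letter as a block, 33 without arrays carrying markers of another tissue and 23 with only the groups compared. Leaving out 1 array gave 14 (FLTC), 18 (FLTD), 40 (FLTB), 60 (FLTA), 54 (VIVD), 55 (VIVB), 65 (VIVC), 70 (VIVA), 61 (FDSB), 63 (FDSC) or 185 (FDSA). In these repeats 13 of 16 named calls ended, all but those of Sftpd, Fkbp5 and Tube1, with adjusted p up to 0.14 for Prnd without FLTC.

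Against the vivarium control (n = 4 per group, VIVA and VIVC with muscle markers) Fkbp5 was 4.86-fold higher after flight (9.45 ± 0.32 against 7.16 ± 0.18, log2 fold change 2.28, SE 0.23, adjusted p = 0.002), Nfil3, a repressor of clock output, 4.29-fold higher (8.91 ± 0.22 against 6.81 ± 0.56, adjusted p = 0.0025) and Sftpd 4.16-fold higher. Exoc3l2 was 3.81-fold lower, Dbp 3.78-fold lower and the secretoglobin pseudogene Scgb1d2-ps1 3.53-fold lower. Of the clock genes Npas2 rose 3.83-fold and Per3 fell 3.28-fold, and the clock, cell cycle and lymphocyte lists were not called. Fatty acid synthesis (2 of 19 called, 7 adjusted over the list alone, list adjusted p = 3.8e-07) and glucocorticoid response (2 of 9, 3 adjusted over the list alone, 0.00013) rose, each with adjusted p = 0.12 with an estimated correlation. Milk fat secretion (list adjusted p = 0.0025) and adipocyte genes (0.0057) lay higher, and skeletal muscle (3.7e-06), endothelium (0.00037) and cholesterol synthesis genes (0.019) lower, with adjusted p = 0.49, 0.72, 0.58, 0.12 and 0.12 with an estimated correlation. The muscle list was not called without VIVA and VIVC (0.54), that of adipocytes without VIVA (0.20) and that of cholesterol synthesis without VIVC (0.12).

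In this contrast limma called 153 probe sets (99 higher, 54 lower), 749 with array weights, 414 with only the groups compared, 91 with the letter as a block and 11 without arrays carrying markers of another tissue. Leaving out 1 array gave 38 (FLTC), 56 (FLTB), 66 (FLTD), 83 (FLTA), 44 (VIVD), 64 (VIVA), 65 (VIVB), 74 (VIVC), 231 (FDSB) or 244 (FDSA). Calls of named genes that ended were Acaca (adjusted p = 0.084), Mt2A (0.15) and Scgb1d2-ps1 (0.052) without FLTC, and Dbp (0.064) and Npas2 (0.11) without VIVD. In both microgravity contrasts 58 probe sets were called in the same direction (46 higher and 12 lower, where chance gives 0.268 and 0.0522) and 0 in opposite directions. These contrasts share the flight arrays, which alone give a correlation across probe sets of 0.50 in simulated unchanged data, equal to the 0.50 observed. The covariance was 0.038 against 0.019 simulated, and with the flight arrays divided so that none was shared the correlation was 0.15 to 0.35. In 50 such simulations at most 0 probe sets were called in both, and with the flight arrays divided in 6 ways 0 to 4 were. The shared number was 10 without arrays carrying markers of another tissue and 23 with only the groups compared. Without 1 array it was 12 (FLTC), 17 (FLTD), 23 (FLTB), 36 (FLTA), 22 (VIVD), 24 (VIVB), 30 (VIVA), 30 (VIVC), 30 (FDSC) or 38 (FDSB).

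Between flight and vivarium control (n = 4 per group) limma called 1 probe set, and 2851 had an unadjusted p under 0.05. It was 1 of the probe sets of the clock output gene Hlf, named after its values were seen, which was lower in the flight control (8.37 ± 0.28 against 9.66 ± 0.17, log2 fold change -1.29, SE 0.14, adjusted p = 0.022). Lists of cell cycle genes (16 of 33 higher adjusted over the list alone, list adjusted p = 2e-13), lymphocyte (1.5e-05) and macrophage markers (0.034, and 0.34 without FDSB) lay higher in the flight control and those of clock genes (3 higher and 11 lower, 1.5e-05) and skeletal muscle (5.7e-06) lower, with adjusted p = 0.39, 0.60, 0.70, 0.39 and 0.60 with an estimated correlation. The lymphocyte mean was higher by 1.35 log2 units and by 0.80 without FDSB, and the muscle list was not called without VIVA and VIVC (0.61). The count was 0 without FLTB, FLTC, FLTD, FDSB, FDSC, VIVB, VIVC or VIVD, 3 without FDSA and 8 without FDSD.

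In pregnant mammary gland the effect of hypergravity against standard gravity was subtracted from that of microgravity against the flight control. Clock, cell cycle and lymphocyte differences may again depend on that control. Fam180a differed by 3.06 log2 units (SE 0.38, n = 4 and 5 per group, adjusted p = 0.0013), the mucosal chemokine Ccl28 by 2.25 (SE 0.39, adjusted p = 0.019), Pex11a by 2.16 (SE 0.36, adjusted p = 0.014) and the kinase Tec by -1.02 (SE 0.19, adjusted p = 0.028). The fatty acid synthesis list differed upwards (12 of 19 adjusted over the list alone, 0 over all probe sets, list adjusted p = 1.6e-11, and adjusted p = 0.0011 with an estimated correlation), with Thrsp at 0.85 (SE 0.18, adjusted p = 0.064) and Fasn at 1.13 (SE 0.25, adjusted p = 0.081). The lists of glucocorticoid response (4 of 9 adjusted over the list alone, list adjusted p = 1.2e-05), clock genes (6 of 20, 1.2e-05) and milk fat secretion (5 of 14, 2.4e-06) differed upwards too, with adjusted p = 0.0059, 0.028 and 0.042 with an estimated correlation. Fibroblast and matrix genes lay higher (2 of 17, 1.5e-07) and cell cycle genes (5 of 33, 1.4e-08) and lymphocyte markers (0.00072) lower, with adjusted p = 0.22, 0.059 and 0.48 with an estimated correlation, and 0.038 for lymphocyte markers at the preset one without FDSB.

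In this contrast limma called 35 probe sets (32 positive, 3 negative), 5 without arrays carrying markers of another tissue, 68 with each array centred on its median and 121 with array weights. Leaving out 1 array gave 16 (FLTC), 20 (FDSC), 21 (FLTD), 57 (M42S) or 79 (M56H, with hepatocyte markers), and 11 lists were called in place of 7 without FDSC or M57S. The calls of Ccl28 (adjusted p = 0.057 without FLTD) and Tec (0.084 without FLTC) ended. Across probe sets the microgravity effect correlated with the hypergravity effect in pregnancy at r = -0.21, and the hypergravity effect in pregnancy with that in lactation at 0.03 in mammary gland and -0.02 in liver.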

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

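The tests of explanations in this part, and the splits of the arrays, were chosen after the results were seen. Chance gives about 1 in 20 groups an array that stands apart by the gap used here, measured against the range of its group.

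M210H and A210H each carried the other tissue's genes, with milk protein means of 3.45 (others of the group 11.1 to 11.33) and 11.28 (3.23 to 3.54) and adipocyte means of 10.48 (7.49 to 8.08) and 7.79 (10.08 to 10.68). A mixture of both tissues on M210H is argued against by its milk protein mean of 3.45, under the 5.75 of the highest other adipose array, and an exchange with the other tissue of another rat by 0 of 38 other arrays lying nearer to the other tissue. An exchange of mammary and adipose material or labels within that rat may account for the pattern, since the arrays correlated at 0.914 and 0.916 with their own tissue and at 0.986 and 0.964 with the other. At 5 of 6 probe sets that separate rats, both arrays showed the state of the liver array of that rat. For each array the livers of 4 other rats matched at least as well, at up to 6 of 6, so an exchange that also involved the same tissue of another rat stays open, and no biological explanation was tested.

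Probe sets lower in the lactating than in the pregnant mammary gland at standard gravity (4835) fell by a median of 1.1 log2 units. Marker list means differed by -0.22 (SE 0.18) for adipocytes, -0.35 (SE 0.15) for fibroblasts, -0.96 (SE 0.10) for macrophages and -0.99 (SE 0.11) for luminal cells. That median is enlarged by choosing probe sets called lower, so it cannot decide on smaller shares of these cells. A change within cells was not tested.

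Cell cycle genes were lower in the lactating mammary gland in hypergravity than at standard gravity (30 of 33). M210H as the cause is argued against by 29 genes called without it, and arrays with muscle or liver markers by 26 called without them. A smaller share of epithelial cells stays open. Without M210H the luminal list mean was 1.15 log2 units higher (SE 0.14) but the milk protein mean lower (-0.28, SE 0.06). An effect of hypergravity may remain as a hypothesis, found and tested on the same data, and the reason was not tested.

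Of 75 means of 5 marker lists, 18 held an array apart from the rest, where chance gives 3.75. Besides the 4 above, milk protein means stood apart in A55H (5.75 against 3.07 to 3.26) and L55H (5.72 against 3.1 to 3.21). Hepatocyte means did in L217H (12.67 against 12.53 to 12.57), M56H (10.57 against 3.63 to 3.94) and FLTB (5.05 against 3.17 to 3.31). Muscle means did in A55H (4.48 against 3.87 to 3.99), A48S (11.77 against 3.87 to 4.16), M212H (7.86 against 3.94 to 4.26), M201S (4.92 against 4.2 to 4.32) and M50H (8.08 against 4.09 to 4.29). Lymphocyte means did in A56H (6.38 against 3.83 to 4.22), A42S (5.55 against 3.64 to 4.14), M219S (5.67 against 3.81 to 4.18) and M60H (6.38 against 4.49 to 4.93). Of 814 combinations of a named gene and a group, 74 held a lone array (9.1%, where chance gives 40.7).

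By direct tests, stage effects differed between gravities at 788 probe sets in mammary gland and 39 in liver. Between tissues they did at 6168 (mammary, liver), 5700 (mammary, adipose) and 25 (liver, adipose), and microgravity and hypergravity effects at 35.

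Each comparison was refitted under splits of its arrays into groups of the same sizes, 35 for 4 arrays against 4 and 100 for the others. The real split alone reached its count for stage in the mammary gland at standard gravity (9614 called, highest other split 3769) and in hypergravity (8640, 7892), hypergravity in the lactating mammary gland (2516, 336) and the difference of these effects (788, 1). The same held in the 5 liver contrasts in the same order, with hypergravity in pregnancy before lactation (193, 1003, 32, 126 and 39, highest others 5, 63, 4, 17 and 28), the differences between tissues (highest others 1739, 1846 and 11) and microgravity against either control (114 and 153, highest others 4 and 1). These splits argue against chance, but at most 100 per comparison, over many comparisons, cannot exclude it. Chance stays open for microgravity against hypergravity (35, 4 splits, highest other 120) and hypergravity in pregnant mammary gland (1, 17 splits, highest other 1413). It also does for the 2 controls (1, 2 splits, highest other 1) and adipose tissue (highest others 4, 1, 22, 3 and 2). With 0 called there, all 100 splits are as large by construction and say nothing. The splits with 7892, 1413 and 120 point to a structure of the samples, and the first sets M210H with 4 pregnant rats.

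For the number of lists called, chance is not excluded. Adipose stage in hypergravity came nearest (15, 3 splits, highest other 17), as 1 of 22 such tests with 0 lists at an estimated correlation. In the order above the splits with as many lists were 34, 98, 49, 88 and 69 in mammary gland (6, 2, 6, 9 and 7 lists, highest others 10, 17, 12, 16 and 17) and 6, 12, 8, 47 and 9 in liver (9, 8, 6, 6 and 8 lists, highest others 12, 10, 8, 10 and 9). They were 68, 78, 24 and 44 in the other adipose contrasts (7, 6, 12 and 10 lists, highest others 18, 16, 17 and 16), 69, 82 and 71 between tissues (3, 5 and 6 lists, highest others 9, 17 and 14), 15, 15 and 31 in the microgravity set (8, 7 and 5 lists, highest other 12) and 48 for microgravity against hypergravity (7 lists, highest other 15).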

How the results depend on the processing

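Of the alternatives, those without M210H and A210H, without arrays carrying markers of another tissue and the overlaps were chosen after seeing the data. Within 1.5 times the reported value were 565 of 702 repeated counts, 585 of 618 numbers of lists and 136 of 169 overlaps. Of 9164 repeats of named genes 8408 kept direction and side of the threshold, 595 lost the call, 92 gained it, 65 moved and 4 were reversed. Reversed were Lalba for mammary stage in hypergravity (1.23 without arrays carrying markers of another tissue, 1.34 without M210H and A210H, and -1.23 to 1.34 without 1 array, the highest without M210H) and Mgll for mammary stage at standard gravity (0.35 with the mean of all probe sets). Except for fewer groups or arrays in a fit, the cause was not tested. The letters of the microgravity set did not pair its arrays (correlations of -0.15 to 0.08 between arrays of 1 letter). Changes of genes near background signal, and of milk proteins near the top of the scale, are limited by the arrays' range.

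Array weights gave counts of 1826 (mammary difference between gravities), 5347 and 7 (mammary hypergravity in lactation and pregnancy), 347, 107 and 79 (liver stage at standard gravity, hypergravity in pregnancy, difference), 3 (adipose stage in hypergravity), 10118 (mammary minus liver), 749 (microgravity against vivarium), 2 (between controls) and 121 (microgravity against hypergravity), and overlaps of 8339 and 122 (stage at both gravities, mammary and liver) and 114 (stage, mammary and liver). Trend and robust variance gave 1 (adipose stage at standard gravity), 53 and 67 (liver hypergravity in pregnancy, difference) and 3 (between controls). Median centring gave 208 (microgravity against flight control, 88.9% higher in place of 73.7%), 5 (between controls) and 68 (microgravity against hypergravity). Quantile normalization gave 0 (between controls) and an overlap of 21 (hypergravity in lactation). Without dim probe sets counts were 0 (mammary hypergravity in pregnancy) and 12 (liver minus adipose). With the letter as a block they were 43, 91 and 0 (microgravity against flight control and vivarium, between controls).

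Only the groups compared gave 5479 and 0 (mammary stage in hypergravity, hypergravity in pregnancy), 596 and 1 (liver stage in hypergravity, hypergravity in lactation), 6 (liver minus adipose), 23, 414 and 0 (microgravity set) and overlaps of 0 (hypergravity in lactation), 23 (microgravity) and 44 (liver stage). Without arrays carrying markers of another tissue counts were 2 (mammary hypergravity in pregnancy), 33, 11 and 0 (microgravity set) and 5 (microgravity against hypergravity), lists 4 (mammary stage in hypergravity) and 3 (between controls), and the microgravity overlap 10. Without M210H and A210H counts were 1250 (mammary difference) and 1 (adipose stage at standard gravity). With an estimated correlation the lists called, in the order stage at standard gravity, stage in hypergravity, hypergravity in pregnancy and in lactation, and difference, were 1, 0, 0, 3 and 2 in mammary gland, 1, 1, 0, 1 and 1 in liver and 1, 0, 0, 0 and 0 in adipose tissue, 0 in the tissue differences and the microgravity set, and 4 for microgravity against hypergravity.

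Leaving out 1 array gave counts of 515 to 1250 (mammary difference), 0 to 7 (mammary hypergravity in pregnancy), 106 to 323, 639 to 1136, 6 to 51, 34 to 244 and 10 to 119 (liver, in the order above), 0 to 1 (adipose stage at standard gravity), 15 to 42 (liver minus adipose), 14 to 185, 38 to 244 and 0 to 8 (microgravity set) and 16 to 79 (microgravity against hypergravity). Overlaps ran from 7 to 49 (hypergravity in lactation), 12 to 80 (microgravity), 51 to 125 (liver stage) and 29 to 78 (stage, mammary and liver). Lists ran from 5 to 11 (mammary hypergravity in pregnancy), 6 to 12 and 9 to 15 (adipose stage), 3 to 8 (liver minus adipose) and 7 to 11 (microgravity against hypergravity).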

Other observations

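Of 18 genes of lactogenic hormone signalling in the mammary gland, 1 rose and 4 fell with lactation at standard gravity (list adjusted p = 0.89) and 4 rose and 4 fell in hypergravity (list adjusted p = 0.50, n = 5 per group). Of 15 genes of glycolysis and glucose uptake 3 rose and 4 fell at standard gravity (list adjusted p = 0.67), and of 12 antioxidant genes 4 rose and 1 fell in hypergravity (list adjusted p = 0.39).

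The following test was chosen after the result was seen. Interferon genes were lower in lactation in liver, and a hypothesis was that rats share an interferon state between tissues. Deviations of the interferon list mean from the group mean correlated between liver and mammary gland at r = 0.49 over 19 rats (permutation p = 0.035, adjusted p = 0.11 over 3 tissue pairs; rho = 0.42, permutation p = 0.077, adjusted p = 0.23), and at 0.31 without the 2 rats farthest from the median. Among 10 pregnant rats r was 0.88 and among 9 lactating rats 0.0. Liver and adipose tissue gave -0.23 (rho -0.33, permutation p = 0.35 and 0.17) and mammary gland and adipose tissue -0.07 (rho -0.04, permutation p = 0.77 and 0.88). The relation did not pass the correction and rests in part on those 2 rats, so a shared state stays open.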
